A study of Homo sapiens with 16 samples.

How the data were processed

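RNA from AsPC-1 cells was hybridised to 16 Affymetrix arrays. Per the labels, total RNA was labelled with biotin by the standard Affymetrix procedure, and the cells had been treated with ICG-001 or its vehicle or transfected with siRNA. The deposited values are intensity values on a linear scale, 1 per probe set and array, and they ran from 0.55 to 19346.51. The method that summarised probes into probe sets and the scaling between arrays are not given in the sources used here. Of 152864 values, 1682 (1.1%) were exactly 1, which is how a lower limit set on background would look in the file. Another 7 values lay below 1, so such a limit did not hold for every value.

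The deposited table held 9554 probe sets. Every one had a coefficient of variation over the 16 arrays of at least 0.40, with 0 probe sets between 0.38 and 0.40 and 856 between 0.40 and 0.42, so the table is a selection of probe sets by their variation. Genes that varied little over the 16 arrays were therefore outside all counts, and each percentage of genes refers to this selection. The table of probe genes listed 1 gene for 6442 probe sets, several genes for 252 and none for 2860. Symbols of 6432 probe sets were matched to current symbols through their gene identifiers. The 3112 probe sets without 1 named gene were left out of the comparisons and counted apart.

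The number 16 was added to each intensity before taking log2, which damps differences between values near background and makes the size of a change depend on that number where a group lies below it. The rule set for scaling was to keep the authors' scaling unless the medians of the arrays differed by more than 0.5 on that log2 scale. They differed by 0.64, and quantile normalization over the 16 arrays was applied. The limit was passed only between the drug arrays and the siRNA arrays. Medians ranged over 0.28 among the arrays with ICG-001 or DMSO and over 0.02 among the siRNA arrays, both under 0.5. The probe set with the highest mean log2 value was then kept for each gene, giving 5250 genes, 936 of which had more than 1 probe set. All stated fold changes are on the log2 scale after this normalization unless another scaling is named, whereas stated intensities are the deposited ones, so the ratio of a pair of printed intensities differs from the printed fold change.

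Each group was a term in a single linear model fitted to all 16 arrays with limma 3.58.1 in R 4.3.3, with an intensity trend in the prior spread. The model left 10 residual degrees of freedom and the prior added 7.84, and this shared spread carries the comparison of 2 arrays with 2. Tests were two-sided, and p-values were adjusted by the Benjamini-Hochberg method over the genes of each comparison. A gene was counted as risen or fallen at an adjusted p under 0.05. The labels call the arrays of a group biological replicates and do not say whether they came from separate cultures or days. The number of arrays limits the precision of every value.

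Gene lists were tested with camera at a preset correlation between genes of 0.01, and again with the correlation estimated from the data. Lists with fewer than 3 measured genes were not tested, which left 21 lists. Their 63 tests in the 3 main comparisons were adjusted together, and the 63 tests in the other comparisons were adjusted together. A further test, fry, asks only whether the genes of a list move one way on balance. Counts of list members use the adjustment over all 5250 genes, and a count adjusted over the list alone is given where it differs from a stated count. They cover measured members only. These were 23 of 42 listed stress response genes, 14 of 50 for DNA replication, 4 of 50 for mitosis and 15 of 32 Wnt targets. Absent members may have varied little, and a treatment effect itself adds to the variation by which probe sets were selected. Such counts thus do not describe whole pathways. Lists of markers for acinar, islet, fibroblast, endothelial and leukocyte cells were counted but not part of those tests. The array's control probe sets for the ends of GAPDH and ACTB transcripts, which bear on RNA quality, were not analysed here. Overlaps of called genes were tested with the two-sided Fisher's exact test, and correlations across genes were computed as description.

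The samples' groups, the model, the gene lists and the rule for scaling were fixed before the data were examined. So was the rule for named genes. For each main comparison it took the 10 largest rises and the 10 largest falls among called genes whose arrays did not overlap between the groups and whose mean log2 value in the higher group was above 4.78, the 25th percentile of all genes. It added up to 4 called members with the largest change from each list past its test or with at least 3 called members. CTNNB1, CREBBP, EP300, AXIN2, MYC, CCND1, BIRC5 and CDKN1A were to be named wherever measured. For the other comparisons it took the 5 largest changes each way. Genes, or values of a gene in a further comparison, that lie outside this rule are said to be named after they were seen.

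Other settings tried were centring each array on its median, adding 1 or 64 in place of 16, dropping the dimmest 25% of genes, a fit without the intensity trend or with a robust spread, array quality weights, a replicate block, the mean of a gene's probe sets, all probe sets, each comparison's own arrays, a 2-fold minimum, an adjusted p under 0.01 and leaving out each array in turn. The deposited scaling and quantile normalization within each experiment were chosen after seeing the data. The procedure was tested on simulated data with the real group sizes. It recovered 94% of genes changed 2-fold at 6 h, 86% at 24 h and 72% in the siRNA comparison, and 3.7%, 4.8% and 5.2% of the genes it called there were unchanged ones. The simulated noise was normally distributed, with a single spread per gene shared by all groups, and was added to values already normalized. The simulation therefore tested neither the normalization nor the equal spread of groups that the siRNA comparison relies on.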

Results

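Expression was measured in AsPC-1, a human pancreatic adenocarcinoma cell line, in a drug experiment and a separate knockdown experiment. In the drug experiment the cells received 10 µM ICG-001, a small molecule described to bind the coactivator CBP and block its contact with β-catenin, or the vehicle DMSO, for 6 h or 24 h, with 3 arrays in each of these 4 groups. In the knockdown experiment the cells were transfected with 20 nM of a control siRNA or of an siRNA against CTNNB1, the gene for β-catenin, and were read at 48 h, with 2 arrays per group. The median intensity was 20.6 to 28.6 on the 12 arrays of the drug experiment and 12.7 to 13.05 on the 4 arrays of the knockdown experiment. Mean intensity was 163.7 to 178.9 on the arrays with ICG-001, 131.7 to 136.8 on those with DMSO and 105.5 to 109.6 on the siRNA arrays. The number of arrays limits the precision of every comparison.

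No probe set listed for CTNNB1 alone was among those analysed here, so the knockdown could not be checked on its own target. The same holds for the Wnt target genes AXIN2, MYC and CCND1 and the CBP-related gene EP300. CREBBP, which encodes CBP, was read by a dim probe set with an intensity of 13.3 ± 0.926 with control siRNA and 4.04 ± 0.99 with CTNNB1 siRNA (mean ± SD, n = 2). Its fitted log2 change there was -0.76 ± 0.20 (± SE, adjusted p = 0.019), and -0.55 (adjusted p = 0.154) in the deposited scaling. That call also ended without control siRNA replicate 2 (-0.72, adjusted p = 0.0819), without CTNNB1 siRNA replicate 2 (-0.69, adjusted p = 0.0934), on the 4 siRNA arrays alone (adjusted p = 0.3) and with 1 in place of 16 added before log2 (-1.72, adjusted p = 0.0715). With 64 added it was -0.28. For CREBBP with ICG-001 the change was -0.61 ± 0.17 at 6 h (adjusted p = 0.0144). It was -0.47 without DMSO 6 h replicate 1 (adjusted p = 0.104), -0.55 without ICG-001 6 h replicate 1 (adjusted p = 0.0769) and -0.60 without DMSO 6 h replicate 2 (adjusted p = 0.0505). With 1 added before log2 it was -1.76 and with 64 added -0.21, both of its groups lying under an intensity of 16 (14.7 with DMSO and 3.4 with ICG-001). At 24 h it was -0.17 ± 0.17 (adjusted p = 0.604), and -0.11 in the deposited scaling.

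The scaling matters for the brightest genes of the ICG-001 comparisons. Among the 525 genes of the brightest 10%, the median log2 change with ICG-001 was -0.19 at 6 h and -0.13 at 24 h after quantile normalization, against 0.13 and 0.22 in the deposited scaling. The median over all 5250 genes at 24 h was -0.02 after quantile normalization and 0.09 in the deposited scaling. For a gene given by name in the 3 main comparisons, the deposited value stands beside the main one where that scaling ends the call, turns its sign or moves its size by more than 1.5 times. List counts in these comparisons are given in that scaling too where they differ.

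ICG-001 at 6 h raised 22 of 23 measured genes of the stress response list and lowered 11 of 14 of the DNA replication list and 9 of 15 of the Wnt target list. Each list had an adjusted p under 0.05, also with an estimated correlation. CHAC1, a glutathione-degrading enzyme induced through the transcription factor ATF4, rose by 5.79 ± 0.21 on the log2 scale, from an intensity of 5.89 ± 2.10 with DMSO to 1380 ± 24.4 with ICG-001 (mean ± SD, n = 3). Its DMSO intensity lay below the 16 added before log2, so the size of this change depends on that number. It was 7.53 with 1 added and 4.15 with 64 added. ASNS, asparagine synthetase, rose by 2.75 ± 0.11, from 1300 ± 20.1 to 12000 ± 22.8. GDF15, a stress-induced cytokine, rose by 4.04 ± 0.08, SESN2, a stress-induced regulator of mTOR signalling, by 3.29 ± 0.06 and ULK1, a kinase that starts autophagy, by 2.72 ± 0.10. The other largest rises were those of KIF21B (2.53 ± 0.15), TSC22D3 (2.37 ± 0.07), CTH (2.26 ± 0.07), IL1A (2.01 ± 0.12) and LURAP1L (2.00 ± 0.09).

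Among the largest falls at 6 h, SOSTDC1, a secreted antagonist of BMP and Wnt ligands, fell by 2.44 ± 0.20, from an intensity of 145 ± 27.2 to 12.8 ± 7.79 (n = 3), a size that was -3.51 with 1 added before log2 and -1.38 with 64 added. SKP2, a ubiquitin ligase subunit that marks CDK inhibitors for degradation, fell by 1.77 ± 0.05, the iron exporter SLC40A1 fell by 1.77 ± 0.07 and the transcription factor FOXA1 fell by 1.52 ± 0.10. DFFB, NREP, FAM111B, NR0B2, SYNM and MSX1 fell by 1.41 to 1.73. In each of these 20 genes, all 3 arrays with ICG-001 lay beyond all 3 with DMSO, a condition of their choice. Of 5250 genes, 724 passed the test at 6 h, of which 292 rose and 432 fell (40.3% rose). The deposited scaling gave 650 genes with 406 risen and 244 fallen (62.5% rose), so the balance of rises and falls turned with the scaling. A change of at least 2-fold was found in 113 of the 724 genes, 63 up and 50 down.

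In the unfolded protein and integrated stress response list, 22 of 23 measured genes rose at 6 h and 1 fell (camera adjusted p = 2.61e-43, and adjusted p = 0.000144 with an estimated correlation). Its largest rises were those of CHAC1, SESN2, ASNS and CTH. HSP90B1, an endoplasmic reticulum chaperone named here after its value was seen, was the gene that fell (-0.55 ± 0.09), and in the deposited scaling it stood at -0.20 (adjusted p = 0.294). Of 12 measured genes in the list of CDK inhibitors and p53 targets, 8 rose and 1 fell (adjusted p = 8.8e-10, and 0.00167 as the adjusted p with an estimated correlation). The list shares SESN2 with the stress list, and its other examples were GDF15, CCNG2 (1.48 ± 0.09) and CDKN2B (0.93 ± 0.10). CDKN1A, which encodes a CDK inhibitor, rose by 0.86 ± 0.08 (1.41 in the deposited scaling), from 1700 ± 81.3 to 4530 ± 148. MDM2, a p53 target in the same list, stood at -0.04 (0.07 in the deposited scaling, past the test in neither), and AEN, an exonuclease, was the gene that fell (-0.66 ± 0.07, and -0.25 in the deposited scaling), both named after their values were seen.

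Of 14 measured genes for DNA replication and the G1/S transition, 11 fell and 0 rose at 6 h (adjusted p = 1.07e-12, and adjusted p = 0.000327 with an estimated correlation). CDC25A, a phosphatase that activates CDKs, fell by 1.37 ± 0.09. The origin recognition subunit ORC1 fell by 1.25 ± 0.08, cyclin gene CCNE2 fell by 1.17 ± 0.05 and the polymerase subunit POLA2 fell by 1.13 ± 0.11. The deposited scaling gave 10 falls. All 4 measured genes for mitosis, of 50 listed, fell at 6 h (adjusted p = 2.34e-04, and adjusted p = 0.0124 with an estimated correlation). In the deposited scaling only BUB1 did, and the list's adjusted p was 0.0227. BUB1, a spindle checkpoint kinase, fell by 0.85 ± 0.12. The deposited scaling ended the calls of BIRC5 (-0.52 ± 0.05 against -0.10, adjusted p = 0.325), CDK1 (-0.30 ± 0.08 against -0.12, adjusted p = 0.546) and ASPM (-0.54 ± 0.13 against -0.32, adjusted p = 0.16).

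Wnt/β-catenin target genes fell at 6 h in 9 of 15 measured cases and rose in 0 (adjusted p = 3.6e-06, and adjusted p = 0.0401 with an estimated correlation). BMP4, a secreted ligand, fell by 1.40 ± 0.10. RNF43, a ubiquitin ligase that removes Wnt receptors, fell by 1.27 ± 0.10, the transcription factor SOX4 fell by 1.00 ± 0.09 and the receptor LGR5 fell by 0.96 ± 0.12. The deposited scaling gave 5 falls and a list median of -0.13 against -0.41, with an adjusted p of 0.000255. Of 12 measured NF-kB and inflammatory genes, 7 rose and 0 fell (adjusted p = 3.13e-07, and adjusted p = 0.0124 with an estimated correlation), among them the cytokine IL1A and the chemokines CXCL2 (1.73 ± 0.13), CCL20 (1.31 ± 0.06) and CXCL3 (1.18 ± 0.10).

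For 3 further lists at 6 h the call was lost with an estimated correlation. Lysosome and autophagy genes rose in 4 of 10 cases and fell in 1 (5 and 1 when adjusted over the list alone), with an adjusted p of 0.00212 and an adjusted p of 0.105 with an estimated correlation. ULK1, MAP1LC3B (1.03 ± 0.05, and 1.56 in the deposited scaling) and TFEB (0.62 ± 0.07), which act in autophagosome formation and its regulation, were among them. Of 7 measured genes of cholesterol synthesis and uptake, 2 rose, TM7SF2 (0.61 ± 0.12) and INSIG1 (0.40 ± 0.06, and 0.77 in the deposited scaling), and 0 fell (4 and 1 when adjusted over the list alone; adjusted p = 0.0264, and adjusted p = 0.0827 with an estimated correlation). Immediate early and MAPK feedback genes rose in 4 of 13 cases and fell in 2 (adjusted p = 0.0221, and adjusted p = 0.188 with an estimated correlation), with rises of the growth factor gene HBEGF (1.85 ± 0.07) and of ATF3 (1.33 ± 0.10) and a fall of SPRY1 (-0.95 ± 0.10). The deposited scaling gave 5 rises and 0 falls for both the lysosome and the cholesterol list.

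The remaining lists did not pass at 6 h. Of 13 genes of the oxidative stress and xenobiotic list, 4 rose and 4 fell (6 and 4 when adjusted over the list alone; adjusted p = 0.137), and in the deposited scaling 7 rose, 1 fell and the list passed (adjusted p = 0.000375). CYP1A1 (1.82 ± 0.09) and CYP1B1 (0.74 ± 0.07), enzymes induced through the aryl hydrocarbon receptor, rose, whereas heme oxygenase HMOX1 fell by 0.70 ± 0.07. Epithelial genes rose in 3 of 12 cases and fell in 1 (3 and 3 when adjusted over the list alone; adjusted p = 0.458), and the list passed in the deposited scaling (adjusted p = 0.0155). Rises and falls were 3 and 3 of 12 for hypoxia and glycolysis, where VEGFA rose by 1.61 ± 0.06, 2 and 2 of 9 for interferon response, 2 and 2 of 11 for mucins and gastric or intestinal genes, 2 and 1 of 7 for apoptosis regulators, and 1 and 1 of 8 for fatty acid synthesis. Adjusted over the list alone, they were 3 and 4 for hypoxia, 2 and 4 for mucins, 3 and 1 for apoptosis and 1 and 2 for fatty acid synthesis. Counts were 0 and 4 of 21 for mesenchymal and matrix genes, 0 and 2 of 5 for β-catenin partners, 0 and 2 of 4 for heat shock proteins, 0 and 1 of 4 for ribosome biogenesis, and 2 and 0 of 6 for polyadenylated histone genes. In the deposited scaling they were 3 and 0 for epithelial genes, 3 and 1 for hypoxia, 2 and 1 for both interferon response and mucins, 3 and 0 for apoptosis and 1 and 0 for fatty acid synthesis. They were there 1 and 2 for mesenchymal genes and 0 and 1 for β-catenin partners. Of 40 core oxidative phosphorylation genes, 2 were measured, and that list was not tested in any comparison. Median, mean and test differed in sign at 6 h for the interferon, hypoxia and apoptosis lists, none of which passed.

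**Figure D1:**
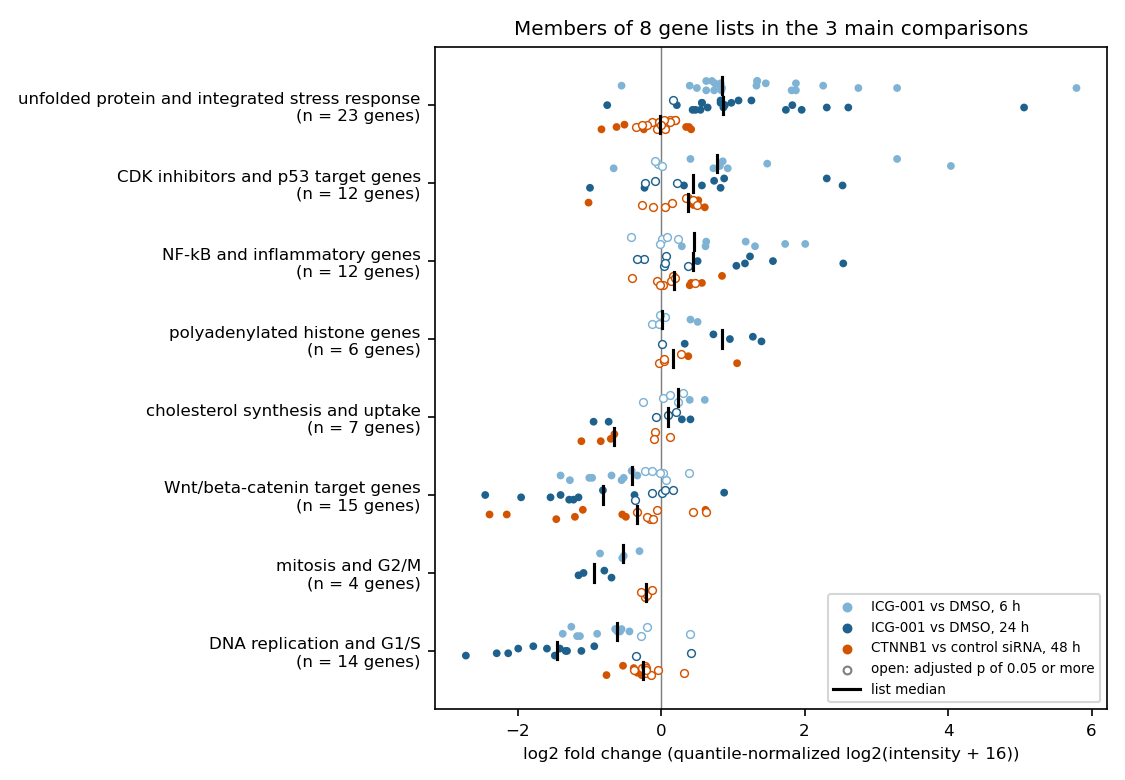
Log2 fold changes of the members of 8 gene lists (dots, 1 per gene; filled when the gene's adjusted p was under 0.05) with list medians (black bars), for ICG-001 against DMSO at 6 h and 24 h and CTNNB1 against control siRNA at 48 h, after quantile normalization. The stress response list has medians of 0.85, 0.87 and -0.02, and the DNA replication list -0.62, -1.45 and -0.25.

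ICG-001 at 24 h raised 21 of 23 stress response genes and 5 of 6 polyadenylated histone genes and lowered 12 of 14 replication genes and 9 of 15 Wnt target genes. Each list had an adjusted p under 0.05, also with an estimated correlation. CHAC1 rose by 5.06 ± 0.21 (6.33 with 1 added before log2 and 3.65 with 64, its DMSO intensity being 13 ± 10.4) and ASNS by 2.61 ± 0.11, to an intensity of 12000 ± 195 from 1490 ± 26.5 (mean ± SD, n = 3). The xenobiotic enzyme CYP1A1 rose by 3.41 ± 0.09, from 254 ± 19.4 to 3640 ± 103, and S100P, a calcium-binding protein, by 2.74 ± 0.06, from 722 ± 33.9 to 6760 ± 206. KIF21B rose by 2.66 ± 0.15, IL1A by 2.54 ± 0.12, GDF15 by 2.53 ± 0.08, DHRS2 by 2.37 ± 0.13, SESN2 by 2.31 ± 0.06 and FNDC4 by 2.24 ± 0.17. SOSTDC1 fell by 3.74 ± 0.20, from 399 ± 18.6 to 20.4 ± 5.91.

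Other large falls at 24 h were those of the galectin gene LGALS2 (-3.05 ± 0.08), FAM111B (-2.86 ± 0.10), the transcription factor MYB (-2.77 ± 0.17), TM4SF4 (-2.56 ± 0.08) and APLP1 (-2.39 ± 0.11). The matrix metalloproteinase MMP7, a Wnt target gene, fell by 2.45 ± 0.15, from 1670 ± 69.6 to 399 ± 18.6. CCNE2 fell by 2.72 ± 0.05, from 1790 ± 25.3 to 345 ± 8.38, and GINS2, a subunit of the replicative helicase, fell by 2.29 ± 0.06. The histone chaperone ASF1B fell by 2.47 ± 0.44, and fell by 1.56 without DMSO 24 h replicate 3, on which its intensity was 12580.62 (DMSO mean ± SD 5270 ± 6330, n = 3). Of 5250 genes, 1076 passed at 24 h, of which 484 rose and 592 fell (45% rose). The deposited scaling gave 740 rises and 385 falls among 1125 genes (65.8% rose), and centring each array on its median gave 544 and 553 (49.6% rose). A change of at least 2-fold was found in 254 of the 1076 genes, 119 up and 135 down.

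At 24 h the stress response list had 21 rises and 1 fall among 23 genes (adjusted p = 1.7e-24, and adjusted p = 0.00092 with an estimated correlation). PSAT1, an enzyme of serine synthesis, rose by 1.96 ± 0.09, and HSP90B1, named after its value was seen, was again the gene that fell (-0.75 ± 0.09, and -0.46 in the deposited scaling, where 22 rose and 1 fell). DNA replication genes fell in 12 of 14 cases and rose in 0 (adjusted p = 3.1e-17, and adjusted p = 0.000144 with an estimated correlation). CDC25A fell by 2.13 ± 0.09 and the helicase subunit MCM6 fell by 1.99 ± 0.10, besides CCNE2 and GINS2. The 4 measured mitosis genes, of 50 listed, fell (adjusted p = 3.78e-05, and adjusted p = 0.0103 with an estimated correlation). They did so in the deposited scaling too. BUB1 fell by 1.08 ± 0.12, CDK1 fell by 0.79 ± 0.08 and ASPM fell by 0.69 ± 0.13 (-0.44 in the deposited scaling). BIRC5, which encodes survivin and is on the Wnt and apoptosis lists as well, fell by 1.15 ± 0.05 (-0.69 in the deposited scaling), from an intensity of 2310 ± 97.1 to 1420 ± 31.3.

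Wnt target genes at 24 h fell in 9 of 15 cases and rose in 1 (adjusted p = 6.09e-06, and adjusted p = 0.0401 with an estimated correlation). MMP7, LGR5 (-1.95 ± 0.12), SOX4 (-1.54 ± 0.09) and BMP4 (-1.40 ± 0.10, and -0.91 in the deposited scaling) fell, while TIAM1, an exchange factor named after its value was seen, rose by 0.88 ± 0.22. CDK inhibitor and p53 target genes rose in 7 of 12 cases and fell in 2 (8 and 3 when adjusted over the list alone; adjusted p = 0.00128, and adjusted p = 0.0401 with an estimated correlation). CDKN1C rose by 0.88 ± 0.11 and CDKN1A by 0.74 ± 0.08 (1.21 in the deposited scaling), and AEN fell by 0.99 ± 0.07 (-0.55 in the deposited scaling). The other gene that fell, the death receptor TNFRSF10B, named after its value was seen (-0.23, adjusted p = 0.023), stood at 0.05 (adjusted p = 0.73) in the deposited scaling, and leaving out any of 4 of the 6 arrays ended its call (-0.21, adjusted p = 0.0943, without ICG-001 24 h replicate 3). NF-kB and inflammatory genes rose in 6 of 12 cases and fell in 0 (7 and 1 when adjusted over the list alone; adjusted p = 6.69e-05, and adjusted p = 0.0401 with an estimated correlation), with IL1A, IL1B (1.56 ± 0.08), IL32 (1.24 ± 0.13) and CXCL2 (1.17 ± 0.13). In the deposited scaling rises and falls were 2 and 8 for Wnt targets, 8 and 1 for CDK inhibitors and p53 targets and 8 and 0 for NF-kB genes.

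Polyadenylated histone genes rose in 5 of 6 measured cases at 24 h (adjusted p = 6.69e-05, and adjusted p = 0.0104 with an estimated correlation). H2AC6 rose by 1.40 ± 0.10, H2BC5 by 1.28 ± 0.07, H2BC21 by 0.96 ± 0.13 and H4C8 by 0.73 ± 0.15. Lysosome and autophagy genes rose in 4 of 10 cases and fell in 0 (4 and 1 when adjusted over the list alone; adjusted p = 0.021, and adjusted p = 0.188 with an estimated correlation), with ULK1 at 1.87 ± 0.10 and WIPI1 at 1.05 ± 0.14, and in the deposited scaling 5 rose and 0 fell. The oxidative stress and xenobiotic list rose in 5 of 13 cases and fell in 2 (adjusted p = 0.0492, and adjusted p = 0.204 with an estimated correlation), and in the deposited scaling 8 rose and 1 fell. Besides CYP1A1, its members CYP1B1 (0.91 ± 0.07) and AHRR (0.67 ± 0.07, and 1.25 in the deposited scaling) rose, all of which are induced through the aryl hydrocarbon receptor, while the glutathione peroxidase GPX2 fell by 1.02 ± 0.18.

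In the lists that did not pass at 24 h, rises and falls were 4 and 2 of 12 for hypoxia and glycolysis, 3 and 2 of 9 for interferon response, 3 and 2 of 13 for immediate early genes, 3 and 3 of 12 for epithelial genes, 4 and 2 of 11 for mucins and gastric or intestinal genes, 1 and 4 of 7 for apoptosis regulators and 2 and 2 of 7 for cholesterol synthesis. Counts were 0 and 3 of 8 for fatty acid synthesis, 0 and 4 of 21 for mesenchymal and matrix genes, 0 and 2 of 5 for β-catenin partners, and 0 and 1 of 4 for both heat shock proteins and ribosome biogenesis. Adjusted over the list alone, they were 3 and 3 for immediate early genes, 1 and 5 for apoptosis regulators and 1 and 3 for fatty acid synthesis. The deposited scaling ended or turned the one-sided falls of some lists, with 2 and 2 for fatty acid synthesis, 2 and 1 for mesenchymal genes and 0 and 0 for β-catenin partners. It gave 5 and 1 for both hypoxia and mucins, 4 and 2 for both immediate early and cholesterol genes, 3 and 1 for epithelial genes and 2 and 3 for apoptosis regulators. VEGFA rose by 1.27 ± 0.06 and the glycolytic enzyme TPI1 fell by 1.47 ± 0.07. The keratin gene KRT7 fell by 1.35 ± 0.09, FOXA1 fell by 1.95 ± 0.10 and the collagen gene COL5A2 fell by 1.15 ± 0.11. SCD, a fatty acid desaturase, is a case where the direction turned: it stood at -0.42 ± 0.04 (adjusted p = 3.64e-07) after quantile normalization, at 0.17 (adjusted p = 0.00801) in the deposited scaling and at 0.04 with each array centred on its median. Median, mean and test differed in sign for the cholesterol, interferon, heat shock and mucin lists at 24 h.

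**Figure D2:**
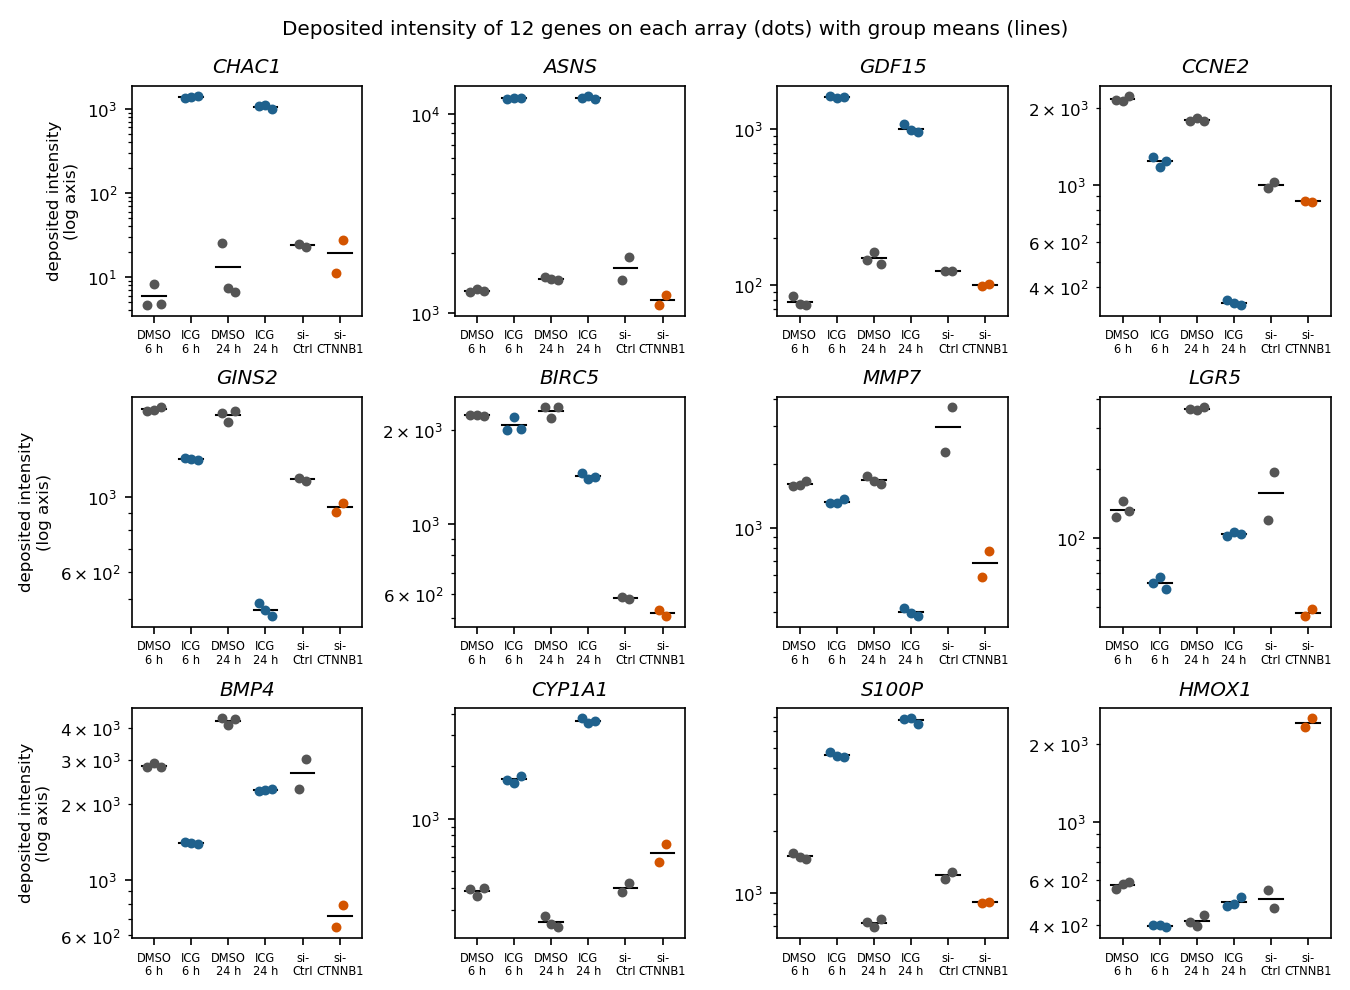
Deposited intensity (log axis) of 12 genes on each of the 16 arrays (dots) by group, with lines at the group means. CHAC1 has a mean intensity of 5.89 with DMSO and 1380 with ICG-001 at 6 h, and MMP7 has 2970 with control siRNA and 681 with CTNNB1 siRNA.

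Of the 724 genes called with ICG-001 at 6 h, 599 were also called at 24 h. Of these 599, 582 (97.2%) changed the same way, 237 up and 345 down, where 26.9 and 48.7 would be shared if the lists were independent. Across the 5250 genes the log2 changes had a Pearson r of 0.642 and a Spearman rho of 0.428; genes are not independent replicates. A test of the difference between the responses found 410 genes, with 204 more positive and 206 more negative at 24 h. In the deposited scaling 268 were more positive and 197 more negative, a share of 57.6% against 49.8%. DNA replication genes had the clearest difference among the lists, with 11 of 14 more negative at 24 h (12 when adjusted over the list alone; adjusted p = 2.43e-17, and adjusted p = 0.000219 with an estimated correlation). CDK inhibitor and p53 target genes were more negative in 6 of 12 cases and more positive in 0 (6 and 1 when adjusted over the list alone; adjusted p = 4.34e-06, and adjusted p = 0.0107 with an estimated correlation), with GDF15 at 4.04 at 6 h and 2.53 at 24 h. Polyadenylated histone genes were more positive in 4 of 6 cases (5 when adjusted over the list alone; adjusted p = 4.34e-06, and adjusted p = 0.00638 with an estimated correlation). Apoptosis regulators were more negative in 3 of 7 and more positive in 0 (adjusted p = 0.00028, and 0.0174 with an estimated correlation). For mitosis genes it was 2 and 0 of 4 (0.00419 and 0.0488), and for stress response genes 7 and 2 of 23 (14 and 2 over the list alone, 4.34e-06 and 0.0513). The Wnt target, cholesterol, immediate early and mucin lists also passed, but only at the preset correlation.

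Single genes with large differences between 24 h and 6 h included CRISPLD2, a secreted matrix-associated protein that stood at -0.06 at 6 h (0.27 with adjusted p = 0.0532 in the deposited scaling) and rose by 2.19 at 24 h (difference 2.25 ± 0.11). DHRS2 (1.82 ± 0.19), CSTA (1.72 ± 0.24, and 2.48 with 1 or 0.95 with 64 added before log2), the collagenase MMP1 (1.69 ± 0.21) and the dim CEACAM7 (1.68 ± 0.34, and 4.08 with 1 or 0.63 with 64 added before log2) were also more positive at 24 h. LGALS2 (-2.04 ± 0.11), APLP1 (-1.94 ± 0.15), TM4SF4 (-1.87 ± 0.11), MYB (-1.77 ± 0.24) and MMP7 (-1.76 ± 0.21) were more negative. For MYB the difference lay in the controls. Its intensity was 106 at 6 h and 355 at 24 h with DMSO, but 46.4 and 50.2 with ICG-001, values chosen after they were seen. The 6 h and 24 h values of CRISPLD2 and the 6 h value of MMP7 were chosen after they were seen. MMP7 stood at -0.69 at 6 h (adjusted p = 0.00183, and -0.28 with adjusted p = 0.18 in the deposited scaling) and fell by 2.45 at 24 h.

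Time in DMSO alone changed 453 genes between 6 h and 24 h, the background for the time course, with 246 risen and 207 fallen (54.3% rose, and 61.3% in the deposited scaling). CAVIN2, a caveola protein, rose by 2.37 ± 0.12, from an intensity of 94.4 ± 9.90 to 487 ± 42.8 (n = 3), and the nuclear receptor NR0B2 rose by 1.95 ± 0.14. MYB rose by 1.74 ± 0.17, the mTOR inhibitor DEPTOR by 1.71 ± 0.12 and RGCC by 1.59 ± 0.10. The trefoil peptide TFF1 fell by 1.93 ± 0.12, the smooth muscle protein TAGLN fell by 1.86 ± 0.12, IL32 fell by 1.5 ± 0.13, S100A2 fell by 1.38 ± 0.09 and S100P fell by 1.16 ± 0.06. MYB, S100P and NR0B2 thus moved in the control cells as well, and their ICG-001 changes at 24 h of -2.77, 2.74 and -2.25 (the last named after it was seen) are relative to those shifted controls. So is the 24 h rise of IL32 (1.24), whose intensity was 225 with DMSO at 6 h, 81.1 with DMSO at 24 h and 216 with ICG-001 at 24 h. For SOSTDC1, intensities at 6 h and 24 h were 145 and 399 with DMSO and 12.8 and 20.4 with ICG-001. Those of FOXA1 were 262 and 605 with DMSO and 94.3 and 177 with ICG-001. The larger 24 h falls of SOSTDC1 and FOXA1 thus came with higher DMSO levels and not with lower ICG-001 levels. LGALS2 (694 and 1360) and GDF15 (77.7 and 148) also shifted in DMSO. These intensities were chosen after they were seen. NF-kB and inflammatory genes fell in 5 of 12 cases over time in DMSO and rose in 0 (5 and 1 when adjusted over the list alone; adjusted p = 0.000147, and adjusted p = 0.0513 with an estimated correlation). DNA replication genes fell in 4 of 14 (adjusted p = 0.00377, and adjusted p = 0.044 with an estimated correlation). Epithelial genes rose in 5 of 12 cases and fell in 1 (adjusted p = 0.0018, and adjusted p = 0.075 with an estimated correlation). Interferon response genes rose in 2 of 9 and fell in 0 (adjusted p = 0.0222, and adjusted p = 0.169 with an estimated correlation). Wnt target genes rose in 5 of 15 cases and fell in 1 (6 and 1 when adjusted over the list alone; adjusted p = 0.00413, and adjusted p = 0.169 with an estimated correlation). Named after their values were seen, LGR5 (1.49 ± 0.12), SOX4 (0.79 ± 0.09), BMP4 (0.51 ± 0.10) and RNF43 (0.47 ± 0.10) rose and CD44 (-0.32 ± 0.07) fell. TNFRSF19, named likewise, stood at 0.52 ± 0.16 (adjusted p = 0.0452), a call that ended without any 1 of the 6 arrays (adjusted p up to 0.165). The ICG-001 falls of LGR5, SOX4 and BMP4 at 24 h are thus relative to controls in which these genes had risen.

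With CTNNB1 siRNA at 48 h, 4 of 7 measured genes of cholesterol synthesis and uptake fell (adjusted p = 9.74e-05, and adjusted p = 0.0106 with an estimated correlation). Wnt target genes fell in 7 of 15 cases, but that list did not pass with an estimated correlation (adjusted p = 3.06e-05, and adjusted p = 0.0553 with an estimated correlation). MMP7 fell by 2.39 ± 0.18 on the log2 scale, from an intensity of 2970 ± 986 with control siRNA to 681 ± 130 with CTNNB1 siRNA (mean ± SD, n = 2), and BMP4 fell by 2.15 ± 0.12, from 2650 ± 501 to 719 ± 104. HMOX1, heme oxygenase, rose by 2.41 ± 0.09, from 506 ± 55.7 to 2410 ± 131. KRT23, a keratin, fell by 2.32 ± 0.11, PPP1R1B, a phosphatase inhibitor, fell by 2.30 ± 0.17 and GPX2, a glutathione peroxidase, fell by 2.25 ± 0.22. LONRF2 (-1.91 ± 0.14), PXYLP1 (-1.80 ± 0.12), ARSD (-1.71 ± 0.18), MYB (-1.69 ± 0.21) and the receptor FGFR2 (-1.56 ± 0.25) followed. Besides HMOX1, MMP19 (2.01 ± 0.15), ARHGDIB (1.79 ± 0.14), FAM83A (1.72 ± 0.16), GUCA2B (1.67 ± 0.20), COL5A3 (1.66 ± 0.20), THBS1 (1.54 ± 0.06) and the cholesterol exporter ABCA1 (1.51 ± 0.15) rose. ARSD, MMP19 and GUCA2B each had a group under an intensity of 16, and their changes were -3.19, 2.68 and 3.48 with 1 added before log2 and -0.76, 1.19 and 0.74 with 64 added.

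Further siRNA values depended on single arrays. IL11RA rose by 1.69 ± 0.34, and by 0.89 without control siRNA replicate 2. DUSP1 stood at 1.58 ± 0.41, at 0.76 (adjusted p = 0.247) without control siRNA replicate 2, at 1.34 (adjusted p = 0.109) without CTNNB1 siRNA replicate 2 and at 2.41 without control siRNA replicate 1. In all, 631 of 5250 genes passed in the siRNA comparison, with 325 risen and 306 fallen (51.5% rose), and 109 changed at least 2-fold. When this comparison used its own 4 arrays alone, 289 genes passed, and with each array centred on its median 414 did. The deposited scaling gave 477 genes, and quantile normalization within each experiment gave 473. On those 4 arrays alone the calls lost included those of IL11RA, GUCA2B, DUSP1, CALD1 and TGFB2 (adjusted p = 0.0599, 0.0589, 0.076, 0.182 and 0.137), besides CREBBP.

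Wnt target genes fell in 7 of 15 cases with CTNNB1 siRNA and rose in 1 (8 and 1 when adjusted over the list alone; adjusted p = 3.06e-05, and adjusted p = 0.0553 with an estimated correlation). Besides MMP7 and BMP4, RNF43 fell by 1.46 ± 0.12 and LGR5 fell by 1.20 ± 0.14. The gene that rose was CD44, an adhesion receptor named after its value was seen (0.62 ± 0.09). Of the 7 cholesterol synthesis and uptake genes, 0 rose. STARD4, a sterol transfer protein, fell by 1.11 ± 0.12. DHCR7, an enzyme of cholesterol synthesis, fell by 0.84 ± 0.13, INSIG1, a sterol sensor, fell by 0.70 ± 0.08 and SQLE, squalene epoxidase, fell by 0.65 ± 0.08. DNA replication genes fell in 5 of 14 cases and rose in 0 (6 and 0 when adjusted over the list alone; adjusted p = 1.29e-04, and adjusted p = 0.0106 with an estimated correlation). ORC1 fell by 0.53 ± 0.10 and the ribonucleotide reductase subunit RRM1 fell by 0.38 ± 0.07, and the deposited scaling gave 3 falls on this list.

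For 5 further lists in the siRNA comparison the call was lost with an estimated correlation. Mesenchymal and matrix genes rose in 6 of 21 cases and fell in 0 (7 and 0 when adjusted over the list alone; adjusted p = 0.00605, and adjusted p = 0.0995 with an estimated correlation), with THBS1, CALD1 (0.91 ± 0.18, and 1.29 with adjusted p = 0.0895 when 1 was added before log2 and 0.49 with 64) and TGFB2 (0.66 ± 0.10). NF-kB and inflammatory genes rose in 4 of 12 and fell in 0 (5 and 0 when adjusted over the list alone; adjusted p = 0.0184, and adjusted p = 0.178 with an estimated correlation), with IL32 (0.85 ± 0.16) and CCL20 (0.40 ± 0.07). Fatty acid synthesis genes fell in 4 of 8 and rose in 0 (4 and 1 when adjusted over the list alone; adjusted p = 0.0221, and adjusted p = 0.075 with an estimated correlation), with the acyl-CoA synthetases ACSL4 (-0.81 ± 0.09, and -0.07 with adjusted p = 0.835 for the mean of its probe sets) and ACSL1 (-0.71 ± 0.12). CDK inhibitor and p53 target genes rose in 4 of 12 and fell in 1 (7 and 2 when adjusted over the list alone; adjusted p = 0.0352, and adjusted p = 0.133 with an estimated correlation). CDKN1A rose by 0.52 ± 0.10 (0.32 without control siRNA replicate 2), and MDM2, the ubiquitin ligase for p53, was the gene that fell (-1.01 ± 0.10, and -0.37 with adjusted p = 0.164 for the mean of its probe sets). Of 4 heat shock genes 1 fell, the co-chaperone STIP1 (-0.77 ± 0.08), with a list adjusted p of 0.0492, an adjusted p of 0.121 with an estimated correlation and an adjusted p of 0.0557 in the deposited scaling. In that scaling rises and falls were 7 and 0 for mesenchymal genes, 5 and 0 for NF-kB genes and 5 and 1 for CDK inhibitors and p53 targets.

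The stress response list did not pass in the siRNA comparison, with 3 rises and 5 falls of 23 (4 and 6 when adjusted over the list alone; adjusted p = 0.513). PSAT1 fell by 0.83 ± 0.11 (-0.27 with adjusted p = 0.0653 for the mean of its probe sets) and CTH fell by 0.51 ± 0.09. ASNS stood at -0.62 ± 0.14 (adjusted p = 0.00459), at -0.37 (adjusted p = 0.0901) without control siRNA replicate 2 and at -0.50 (adjusted p = 0.0616) without CTNNB1 siRNA replicate 1. Mitosis genes had 0 calls of 4 (0 rises and 1 fall when adjusted over the list alone), and BIRC5 stood at -0.19 ± 0.06 (adjusted p = 0.0646). The oxidative stress and xenobiotic list had 4 rises and 3 falls of 13 (adjusted p = 0.848), with HMOX1 and GPX2 moving in opposite directions. Rises and falls were 4 and 1 of 13 for immediate early genes, 3 and 2 of 12 for epithelial genes, 2 and 2 of 12 for hypoxia and glycolysis, 2 and 1 of 9 for interferon response, 2 and 2 of 11 for mucins and gastric or intestinal genes, and 2 and 2 of 10 for lysosome and autophagy. Adjusted over the list alone, they were 3 and 2 for interferon response and 4 and 2 for mucins. Counts were 1 and 2 of 5 for β-catenin partners, 2 and 0 of 6 for polyadenylated histone genes, 0 and 1 of 4 for ribosome biogenesis and 0 and 0 of 7 for apoptosis regulators. The deposited scaling turned the balance for interferon response, to 1 and 2. It gave 3 and 3 for the stress response, 3 and 1 for immediate early genes, 2 and 2 for epithelial genes, 1 and 2 for mucins and 2 and 1 for lysosome. The others were 0 and 1 for β-catenin partners and 1 and 0 for histone genes. KRT7 rose by 1.06 ± 0.11 and the claudin gene CLDN3 fell by 1.32 ± 0.12. Median, mean and test differed in sign for the oxidative stress, epithelial, mucin and apoptosis lists.

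How far drug and knockdown moved the same genes was compared next. The log2 changes with ICG-001 and with CTNNB1 siRNA had a Pearson r across genes of 0.157 at 24 h (Spearman rho 0.128) and 0.0869 at 6 h (rho 0.0795). Of 343 genes called both at 24 h with ICG-001 and with CTNNB1 siRNA, 228 (66.5%) changed the same way. Genes that fell in both numbered 126, with 34.5 if the lists were independent (odds ratio 6.72, Fisher's exact adjusted p = 4.44e-44), and genes that rose in both numbered 102, with 30 if independent (odds ratio 5.44, adjusted p = 1.45e-31). Opposite changes also exceeded independence: 54 genes rose with the drug and fell with the siRNA against 28.2 (odds ratio 2.25, adjusted p = 2.05e-06), and 61 did the reverse against 36.6 (odds ratio 1.91, adjusted p = 3.92e-05). At 6 h, 110 genes fell in both against 25.2 and 63 rose in both against 18.1, out of 275 called in both, and the deposited scaling gave 66 and 97. Opposite changes at 6 h exceeded independence as well, with 44 genes risen with the drug and fallen with the siRNA against 17 (odds ratio 3.18, adjusted p = 3.57e-09) and 58 the reverse against 26.7 (odds ratio 2.64, adjusted p = 9.53e-09). Genes are not independent replicates, so these p-values overstate the evidence. The background matters too: 3027 probe sets (31.7%) had a coefficient of variation under 0.40 within both experiments. If such genes are seldom called in either comparison, the number expected under independence is too low for every pair of directions. This was not tested, and it bears on the overlap of 6 h and 24 h as well.

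Among Wnt target genes, MMP7, BMP4, RNF43 and LGR5 fell both with ICG-001 at 24 h and with CTNNB1 siRNA, RNF43 at 24 h being named after its value was seen. ABCA1 rose with both, by 1.5 with the drug and 1.51 with the siRNA, the drug value named after it was seen. KRT7 fell with the drug and rose with the siRNA, and ARHGDIB stood at -1.43 with the drug at 24 h, named after it was seen, and at 1.79 with the siRNA. VEGFA rose with the drug (1.27 ± 0.06 at 24 h) and fell with the siRNA (-0.80 ± 0.07).

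**Figure D3:**
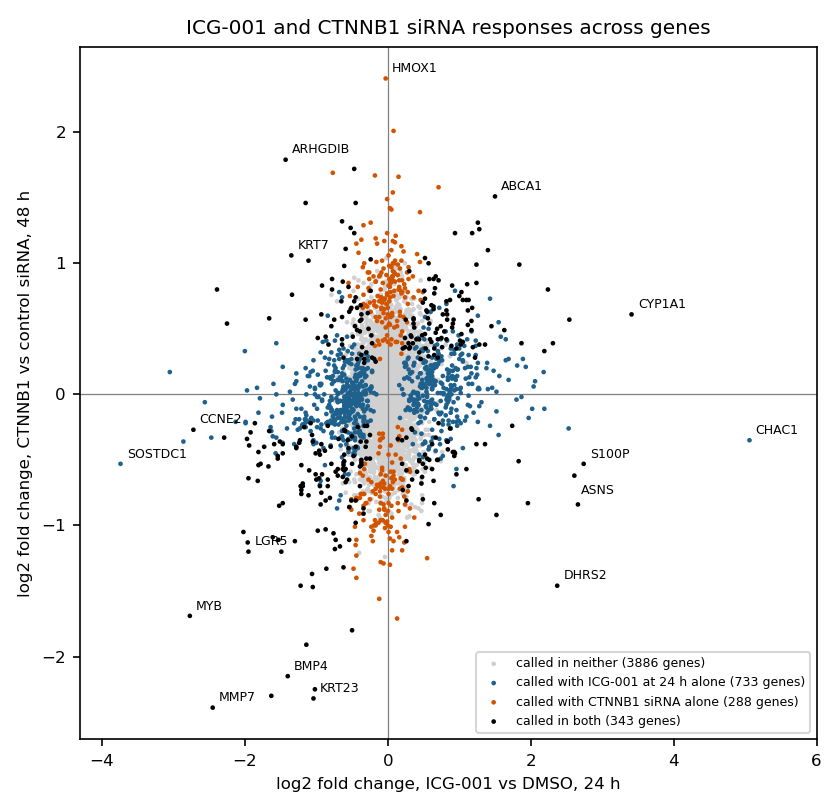
Log2 fold change of 5250 genes (dots) with ICG-001 at 24 h (x axis) and with CTNNB1 siRNA at 48 h (y axis), coloured by whether the adjusted p was under 0.05 in neither (3886 genes), in the drug comparison (733), in the siRNA comparison (288) or in both (343). MMP7 (-2.45 and -2.39) lies low on both axes, CHAC1 (5.06 and -0.35) far along the drug axis and HMOX1 (-0.03 and 2.41) far along the siRNA axis. The smaller value of CHAC1 and of HMOX1 was named after it was seen. That of CHAC1 was -0.21 (adjusted p = 0.769) in the deposited scaling, where that of HMOX1 was 0.23 and passed the test (adjusted p = 0.016).

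A direct test of the difference between the ICG-001 24 h response and the CTNNB1 siRNA response found 835 genes, 376 more positive with the drug and 459 more negative (45% positive, and 63.6% in the deposited scaling). Treatment time and control differ between these arms as well as the agent. The stress response list was more positive with the drug in 20 of 23 genes and more negative in 1 (adjusted p = 1.14e-21, and adjusted p = 0.00193 with an estimated correlation). DNA replication genes were more negative with the drug in 12 of 14 (adjusted p = 4.87e-14, and adjusted p = 3e-04 with an estimated correlation). Wnt target genes were more positive in 3 and more negative in 6 of 15 (adjusted p = 0.196), which does not show that both agents act alike on them. CHAC1 (5.41 ± 0.33, and 6.89 with 1 or 3.82 with 64 added before log2), DHRS2 (3.83 ± 0.21, and likewise 4.72 or 2.67), KIF21B (3.50 ± 0.23, and 4.23 or 2.49), S100P (3.27 ± 0.10) and ASNS (3.23 ± 0.17) differed most toward the drug. ARHGDIB (-3.23 ± 0.18), LGALS2 (-3.21 ± 0.12), SOSTDC1 (-3.21 ± 0.31, and -3.86 with 1 or -2.3 with 64 added before log2), APLP1 (-3.19 ± 0.17) and NR0B2 (-2.79 ± 0.22) differed most the other way, whereas MMP7, named here after its value was seen, differed by -0.06 (adjusted p = 0.909).

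Markers of other cell types were few among the measured genes. Of the marker lists, 2 of 16 acinar, 0 of 14 islet, 6 of 12 fibroblast, 3 of 10 endothelial and 3 of 16 leukocyte genes were measured, and no fibroblast, endothelial or leukocyte marker was called in the 3 main comparisons. In the deposited scaling 1 fibroblast marker, POSTN, rose with ICG-001 at 24 h (0.56, adjusted p = 0.0178, against 0.41 with adjusted p = 0.0588), named after its value was seen. The acinar marker PRSS2, a trypsinogen that was bright in these cultures, fell by 0.46 ± 0.07 with CTNNB1 siRNA, and PLA2G1B, a pancreatic phospholipase, stood at -0.87 ± 0.24 (adjusted p = 0.0216, and -0.62 with adjusted p = 0.158 in the deposited scaling). Its call also ended without control siRNA replicate 1 (-0.75, adjusted p = 0.105) and without CTNNB1 siRNA replicate 2 (-0.68, adjusted p = 0.153). With ICG-001 at 6 h PRSS2 stood at -0.22 ± 0.06 (adjusted p = 0.0139) after quantile normalization and at 0.30 (adjusted p = 0.000178) in the deposited scaling, and at 24 h it stood at 0.11 (adjusted p = 0.276) and at 0.72 (adjusted p = 5.46e-10), so its direction at 6 h depended on the scaling. Its 6 h call also ended without ICG-001 replicate 1 (-0.20, adjusted p = 0.0686) and without DMSO replicate 3 (-0.18, adjusted p = 0.0974). Both marker genes were named after their values were seen.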

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

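Of the tests in this part, the one on array scaling and the one on the brightest genes were chosen after the result was seen; the other tests were written down before their results.

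The ICG-001 response differed between 24 h and 6 h, by a test of the difference itself, in 410 genes. The named genes with the largest differences in log2 change (24 h minus 6 h) were CRISPLD2 (2.25), DHRS2 (1.82), CSTA (1.72), MMP1 (1.69), CEACAM7 (1.68), LGALS2 (-2.04), APLP1 (-1.94), TM4SF4 (-1.87), MYB (-1.77) and MMP7 (-1.76). That of MYB lay in the controls, where it rose with time, its ICG-001 intensity being 46.4 at 6 h and 50.2 at 24 h. Next, 100 splits of the arrays over time within treatment were compared, with the mean time effect removed. Only the real split, 1 of the 100, gave as many genes (407 in this setting, against at most 1 in another split). A random split of these arrays thus seldom gives such a count. The test treats the arrays as exchangeable, so a difference in culture or day shared by the arrays of a group would pass it too. For the ICG-001 comparison at 6 h (724 genes, highest other split 1), at 24 h (1076, highest other 0) and DMSO over time (453, highest other 0), 10 splits of 3 against 3 arrays are too few for a share under 0.05.

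The response to ICG-001 at 24 h and that to CTNNB1 siRNA differed, by a test of the difference itself, in 835 genes. The largest differences (drug minus siRNA) were those of CHAC1 (5.41), DHRS2 (3.83), KIF21B (3.5), S100P (3.27), ASNS (3.23), ARHGDIB (-3.23), LGALS2 (-3.21), SOSTDC1 (-3.21), APLP1 (-3.19) and NR0B2 (-2.79). Both sets of arrays were read against controls of their own.

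Signal also appeared in probe sets that the comparisons left out because no 1 gene was listed for them. Of these 3112 probe sets, 125 changed past the threshold with ICG-001 at 6 h, 250 with ICG-001 at 24 h and 185 with CTNNB1 siRNA. Their p-values were adjusted over all 9554 probe sets. Among the 5250 named genes 724, 1076 and 631 passed, so the unnamed probe sets were called less often.

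The 4 siRNA arrays stood apart from the 12 drug arrays, with a Pearson r of 0.754 across probe sets between control siRNA and DMSO at 24 h as deposited. After quantile normalization r was 0.756, far below the lowest r of 0.958 between groups of the drug experiment. The low r thus remained after scaling of whole arrays was evened out. Since r across probe sets hardly responds to such scaling, this outcome was nearly fixed in advance. A scaling difference besides other causes is not excluded. Selection of probe sets by their variation stays open, since on the 4609 probe sets that vary within the drug arrays r was 0.86, against a lowest value of 0.919 between drug groups. A change of labelling or hybridisation batch may contribute: among probe set pairs of 1 gene that both differed at least 2-fold between control siRNA and DMSO, 16.5% had opposite signs (43 of 261, exact 95% interval 12.2% to 21.5%), against 1.22% (1 of 82, 0.0309% to 6.61%) for ICG-001 against DMSO at 24 h. Transfection and the longer time in culture are biological differences between the experiments that were not tested. Each fold change in the report is against a control of the same experiment, and the test of the drug response against the siRNA response contrasts such fold changes across the experiments after quantile normalization over the 16 arrays.

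In the deposited scaling more genes rose than fell with ICG-001 at 24 h (65.8% of 1125). A single array with a high median, ICG-001 24 h replicate 2, is excluded as the cause, because 63.9% rose without it. Raised background on dim probe sets stays open for the dimmer genes, since the median shift of the dimmest probe sets was 0.14 on that array and -0.01 and 0.04 on the others. Of the called genes in the brightest group of 4 equal groups by level, 63.7% rose, so the excess of rises was not confined to dim genes. That share does not measure background itself. What raised the bright genes on the ICG-001 arrays, an effect of the drug on many genes or the unnamed scaling, was not tested, and quantile normalization removes it by construction.

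Histone genes rose at 24 h with ICG-001 in 5 of 6 members of the fixed list. A general rise of histone transcripts was tested on the 10 measured histone genes outside the list, of which 30% rose (H3C6 by 1.13, H2BC17 by 0.85 and H2AC25 by 0.69, named after their values were seen) and 0 fell. The call of H2BC17 ended without ICG-001 24 h replicate 2 (0.65, adjusted p = 0.0666) and without DMSO 24 h replicate 1 (0.65, adjusted p = 0.0613). The 30% lies between the bounds set for and against a general rise, and 7 of the 10 did not pass. Of those, H1-5, H3C11, H4C10P, H2AC5P, H2AC15 and H2BC3 were dim, with DMSO intensities at 24 h of 9.22, 12.7, 12.8, 14.3, 18.3 and 26.8. H1-6 stood at 43.3, and the genes that rose at 38 (H2BC17), 60.2 (H3C6) and 513 (H2AC25). A rise of the dim genes could go unseen, so the 2 readings cannot be told apart on these genes. Probe sets for members of this family can respond to more than 1 member, which was not tested.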

How the results depend on the processing

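The deposited scaling and quantile normalization within each experiment were chosen after seeing the data. Requiring at least 2-fold left 113 genes with ICG-001 at 6 h, 254 at 24 h, 109 with CTNNB1 siRNA, 77 for 24 h against 6 h, 37 for DMSO over time and 328 for drug against siRNA, fewer by construction. The siRNA count of 631 was 414 with each array centred on its median, 258 with array quality weights, 289 on its own arrays (fewer arrays for the spread) and 336 at an adjusted p under 0.01. It was 477 in the deposited scaling and 473 with quantile normalization within each experiment. Part of the 631 calls thus depends on normalizing both experiments together. Total counts of called genes in the other 5 comparisons stayed within 1.5 times the main count under every other setting run, but their split did not: falls at 6 h (432) were 222 with median centring and 244 in the deposited scaling, 24 h rises (484) and falls (592) were 740 and 385 in the deposited scaling, and genes more negative with drug than siRNA (459) were 269 there. The setting with all probe sets counts probe sets and not genes. It gave 753 probe sets risen at 24 h (484 genes) and 614 more positive with the drug than with the siRNA (376 genes).

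The correlation across genes between 6 h and 24 h (0.642) was 0.401 with 1 added before log2 and 0.743 with 64 added, 0.682 without the dimmest genes, 0.603 on all probe sets, 0.747 on genes above the median level and 0.772 on genes called in either comparison. That between 6 h and siRNA (0.0869) was 0.0393 with 1 added, 0.123 with 64 added, 0.109 with arrays centred on their medians and in the deposited scaling, 0.108 with quantile normalization within each experiment, 0.118 above the median level and 0.121 on called genes. Between 24 h and siRNA (0.157) it was 0.0831 with 1 added, 0.228 with 64 added, 0.213 above the median level and 0.218 on called genes. Adding more damps dim genes and raises these correlations.

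Shared rises of 6 h and siRNA (63) were 41 without the intensity trend, 39 with array weights and 97 in the deposited scaling; shared falls (110) were 54 with median centring, 69 without the trend, 65 with array weights and 66 in the deposited scaling. For 24 h and siRNA, array weights gave 58 shared rises (102) and 71 shared falls (126). The cause was not tested for the weights and the trend. SCD at 24 h reversed from -0.42 to 0.04 with median centring and 0.17 in the deposited scaling, which follows from quantile normalization lowering bright genes on the ICG-001 arrays.

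Leaving out each array in turn gave 623 to 662 genes at 6 h, 934 to 1024 at 24 h, 484 to 669 for siRNA, 343 to 407 for 24 h against 6 h, 371 to 413 for DMSO over time and 733 to 850 for drug against siRNA. An siRNA group left with 1 array was assumed to vary like the other groups. Correlations ranged from 0.617 to 0.647 (6 h and 24 h), 0.071 to 0.0879 (6 h and siRNA) and 0.121 to 0.158 (24 h and siRNA). Shared genes ranged from 43 to 72 and 83 to 109 (6 h, risen and fallen) and from 69 to 122 and 95 to 133 (24 h).

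Replicate numbers did not pair arrays: after removing group means, same-numbered arrays of different drug groups had r of -0.15 to 0.09 and others -0.12 to 0.12, and a block on the number gave 734, 1093, 656, 426, 467 and 878 genes in the order above. With it the xenobiotic list at 24 h (adjusted p = 0.0619), heat shock genes with siRNA (0.0532) and lysosome genes for drug against siRNA (0.0547) lost their calls. Of the tests of lists, 26 lost and 100 kept their side with an estimated correlation, and fry put 37 more past the threshold. In the deposited scaling 4 list tests gained a call and 2 lost one, the latter heat shock genes with siRNA (0.0557) and mucin genes for 24 h against 6 h (0.0537). Over the named genes, called or not, 1417 results kept direction and side of the threshold when an array was left out, 98 lost their call and 1 gained one; over the other settings 2995 kept both, 140 lost their call, 2 gained one and 2 reversed. Low signal over background limits dim genes such as CREBBP and CEACAM7.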

Other observations

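Genes outside the fixed lists moved with both ICG-001 at 24 h and CTNNB1 siRNA; they are named here after their values were seen, and genes are not independent replicates. PPP1R1B fell by 1.63 with the drug and 2.3 with the siRNA, and MYB stood at -2.77 and -1.69. The serine protease KLK7 (-1.61 and -1.09), the chaperone CLU (-1.53 and -1.11), SOWAHA (-1.49 and -1.2), BCL2L15 (-1.96 and -1.13) and LONRF2 (-1.14 and -1.91) fell in both as well. The sulfotransferase CHST2 (1.26 and 1.31), TCIM (1.28 and 1.26), the laminin subunit LAMB3 (1.18, or 1.78 in the deposited scaling, and 1.23) and NTN4 (1.11 and 0.84) rose in both. KIF21B (2.66 and -0.84), DHRS2 (2.37 and -1.46) and LBH (-1.15 and 1.46) changed in opposite directions, but the siRNA call of KIF21B ended without control siRNA replicate 2 (-0.60, adjusted p = 0.0723) and without CTNNB1 siRNA replicate 1 (-0.57, adjusted p = 0.0713).

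Some genes had probe sets called in opposite directions: 2 of 936 genes with several probe sets at 6 h with ICG-001, 9 at 24 h and 3 with CTNNB1 siRNA. At 6 h these were ABCC3 and ARG2, and with the siRNA ERN2, GNG7 and STK32A.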
